A study of Mus musculus with 6 samples.

How the data were processed

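The samples were 6 arrays of lung antigen presenting cells of female mice, 2 each of wild type in room air, wild type in smoke and Spp1-/- in smoke, as assigned by their titles. Per the labels' protocols, RNA was extracted with Trizol and biotinylated cRNA was made with an Ambion MessageAmp kit for Illumina arrays. How the antigen presenting cells were isolated is not given in the sources used here. The submitters' processing notes name limma, without a version.

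The values used were the deposited log2 intensities of 45281 probes. The sorted columns of the 6 arrays differed by at most 0.0036, as quantile normalized values do, and every array had a median of 7.264. The background correction and any offset are not given in the sources used here. A floor of 6.619 compresses the differences of dim probes. A further table with 12 columns of signals and detection p-values was not used, because its column names could not be matched to the samples by their labels. The number of arrays, 2 per group, limits the precision.

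Before the data were examined, the plan was to normalize raw signals with neqc and to filter on detection p. Neither could be done without that table, so the deposited values took its place, with the fallback filter of the plan, the brighter 50% of probes by mean over all arrays. The condition that a named gene be detected could not be applied either. Probe names came from the platform annotation, with symbols updated by Entrez identifier through the RefSeq gene table of GRCm38.p6. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 were not named here. Updated symbols were found for 34807. Named probes covered 19057 genes, of which 12382 were kept, each by its brightest probe. The files name no genome build, so no coordinates are given.

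Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit with 1 coefficient per group over all 6 arrays, eBayes with the default prior). There were 3 residual and 2.24 prior degrees of freedom. The p-values were adjusted by Benjamini-Hochberg over all kept genes and called under 0.05. An exact permutation of 2 against 2 arrays cannot give a p below 0.333, so none was used for single genes. Gene lists were tested with camera at a preset correlation of 0.01 and again with estimated correlations. The test was adjusted over the 21 function and cell type lists with at least 5 measured members. These lists were fixed before the data were examined, when what is known of the study already named Irf7, an interferon gene. The run with estimated correlations rests on the 3 residual degrees of freedom, and its smallest camera adjusted p over these lists was 0.18. Lists with estimated correlations under 0.01 lost their call too, such as cytokines and chemokines (-0.012) and matrix proteases (-0.0058) in smoke against air. A call lost there thus does not show that correlation between genes was the reason. The steps were tested on simulated data for smoke against air, with 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale. Of these, 2%, 44%, 90% and 98% were recovered, with 0 false calls. Far fewer genes were changed there than the 2645 called in the data, and the adjustment is stricter when fewer genes differ. The recovered shares thus may not hold for the data. A simulation of the genotype comparison, added after its result had been seen, changed 36 genes in each of 20 draws per size and gave 34 false calls over all draws at a change of 2 and 34 at 3.

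Genes were named by a rule set beforehand. The rule took the 10 largest changes in each direction among called genes whose groups did not overlap. Where fewer than 5 were called, it took the 5 with the smallest p, said not to pass. It added up to 4 members with the smallest p of each list described, and Spp1 and Irf7. Values for the opposed directions of the first and second comparison were set beside 100 simulations of unchanged groups. The first simulation used 1 common spread. A second, with a spread for each group, was added after the result of the first had been seen, and both are given.

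Alternatives were no filter, the mean of a gene's probes, an intensity trend with a robust prior, array weights, only the groups compared, a replicate block, a 2-fold threshold, estimated correlations and each array left out in turn. Where an array was left out, the lone array of its group was assumed to vary like the other groups. A stricter brightness filter (the 75% quantile of probes), removal of the floor with an offset of 16, and centring on the kept genes were added after the data had been seen.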

Results

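Gene expression was measured on 6 Illumina mouse arrays of antigen presenting cells taken from the lungs of female C57BL/6 mice, with 2 arrays in each of 3 groups. Wild type mice had breathed room air, wild type mice had been given cigarette smoke for 4 months, and mice without Spp1, the gene of the secreted matrix and cytokine protein osteopontin, had been given smoke in the same way. No Spp1-/- mice in room air were among the samples, so a smoke effect in that genotype was not measured. No probe was paired with Spp1 in the annotation used here. The level of the targeted gene, and with it the genotype label, was therefore not checked. The deposited log2 intensities ran from 6.619 to 16.014, with a median of 7.264 over all probes, and 12382 genes in the brighter part of this range were compared. The labels do not say that the 2 arrays of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical. Across all probes, the 2 wild type air arrays correlated with Pearson r = 0.9773, the wild type smoke arrays with 0.9917 and the Spp1-/- smoke arrays with 0.9936. The median SD of a gene was 0.149 in wild type air, 0.091 in wild type smoke and 0.087 in Spp1-/- smoke (log2, n = 2 each).

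The first comparison asked how smoke exposure related to expression in wild type preparations of lung antigen presenting cells. These preparations may hold other lung cells, so a difference may come from the mix of cells as well as from change within cells. On lists of lipid handling and lysosomes, matrix proteases, and cytokines and chemokines, more genes passed upward than downward after smoke, and most genes of lung epithelium, endothelium and fibroblasts passed downward. As groups, these lists passed with a preset correlation and none of them with an estimated correlation (adjusted p between 0.18 and 0.23). Mmp12, the macrophage elastase, stood at 9.41 ± 0.31 (SD, n = 2) in air and 13.35 ± 0.23 in smoke, a 15.3-fold rise. Trem2, a lipid-sensing receptor of macrophages, rose from 9.96 ± 0.04 to 12.84 ± 0.04, or 7.36-fold. Slc34a2, a phosphate transporter of alveolar type II epithelium, was lower in smoke, at 9.27 ± 0.26 against 12.30 ± 0.01. At a limma adjusted p under 0.05, 2645 of the 12382 genes differed, 1371 of them higher and 1274 lower after smoke, and 1295 of the calls were at least 2-fold, 524 higher and 771 lower. The count was 743 without wild type smoke replicate 1 (299 higher, 444 lower), 925 without wild type smoke replicate 2 (362 higher, 563 lower), and 1489 without either of the Spp1-/- arrays in turn (711 higher, 778 lower), which lend only their spread to this fit. Of 101 genes called here among those that the naming rule chose, 39 were lost without wild type smoke replicate 1, 32 without replicate 2 and 10 without either Spp1-/- array.

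The largest rise among the called genes belonged to Ear6, a ribonuclease of the eosinophil-associated family, with a log2 fold change of 5.61 ± 0.23 (SE) and adjusted p = 0.00128. The Ear genes are near-identical copies, so its signal may include other members. Npy, the gene of neuropeptide Y, rose by 4.24 ± 0.15 on the log2 scale (adjusted p = 0.00128), from an air value of 7.15 that lay below the median of all probes. Ptgir, the prostacyclin receptor gene, rose from 8.35 ± 0.15 to 11.70 ± 0.14, and Fabp5, a fatty acid binding protein gene, from 8.62 ± 0.55 to 11.70 ± 0.26. Syngr1 changed by 3.93, Car13 by 3.31, Spsb4 by 3.13 and Fkbp11 by 3.13 on the log2 scale, all upward. Of the 20 genes named for the size of their change, 1 had only a provisional name. Car13 no longer passed without wild type smoke replicate 1 (adjusted p = 0.0553).

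Among the called genes, the largest fall was that of Rasl12, with a log2 fold change of -4.08 ± 0.38 (SE) and adjusted p = 0.00335. Myzap changed by -3.78, Ppp1r3c by -3.67, Tmem178 by -3.57 and Spon2 by -3.56. The flavin monooxygenase gene Fmo1 stood at 12.93 ± 0.12 in air and 9.27 ± 0.02 in smoke. Egfl7, an endothelial gene, stood at 12.78 ± 0.52 and 9.17 ± 0.05, and Adgrf5, a receptor gene of alveolar epithelium and endothelium, at 12.72 ± 0.10 and 9.19 ± 0.04. Wnt2, a secreted signalling protein of lung mesenchyme, changed by -3.69, to a smoke value of 7.25 below the median of all probes, and Mapt by -3.49. Wnt2 missed the threshold without wild type smoke replicate 1 (adjusted p = 0.0545), and Mapt without wild type smoke replicate 2 (adjusted p = 0.0612). Rasl12, Fmo1, Egfl7 and Mapt each had 1 other, dimmer probe with a small change in the opposite direction, between 0.09 and 0.2 on the log2 scale.

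Of 27 measured genes on the list of lipid handling and lysosomal genes of loaded macrophages, 13 rose and 0 fell after smoke, and 18 rose when adjusted over the list alone. The list's median log2 fold change was 0.56 (camera adjusted p = 6.95e-08; adjusted p = 0.18 with an estimated correlation). Besides Trem2, its leading members were Ctsk (cathepsin K), at 13.96 ± 0.01 in air and 15.75 in smoke, Ch25h (cholesterol 25-hydroxylase), at 12.14 ± 0.04 and 14.78 ± 0.33, and Cd63, a lysosomal tetraspanin gene, at 12.61 ± 0.05 and 14.61 ± 0.10. Of 26 genes for matrix proteases and their inhibitors, 9 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.00475; adjusted p = 0.18 with an estimated correlation). Mmp12 and the cathepsin genes Ctsk and Ctsz led the rise, Ctsz from 11.22 ± 0.09 to 12.83 ± 0.04. Timp3, an inhibitor of metalloproteases, was lower at 9.86 ± 0.37 against 12.49 ± 0.12. Without either wild type smoke array, 8 lipid and lysosome genes rose, and the rising protease genes numbered 3 without replicate 1 and 4 without replicate 2. Without either Spp1-/- array they numbered 10 and 5.

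Of 19 inflammatory cytokine and chemokine genes, 9 rose and 1 fell (11 and 2 adjusted over the list alone). Their median was 0.74 (adjusted p = 0.000908; adjusted p = 0.18 with an estimated correlation). Ccl17 rose from 9.69 ± 0.22 to 12.21 ± 0.04, Ccl6 from 11.09 ± 0.21 to 13.42 ± 0.04, Ccl3 from 7.57 ± 0.31 to 10.60 ± 0.05 and Ccl7 from 7.32 ± 0.21 to 10.20 ± 0.31. Without either wild type smoke array 6 of them rose. Of 29 cell cycle genes, 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.48 (adjusted p = 0.000168; adjusted p = 0.28 with an estimated correlation). Among them, Cdca8, Cdc20, Nusap1 and Mcm5 changed by 0.84, 1.05, 1.28 and 0.71. A dimmer probe of Cdca8 (mean 6.99) and of Nusap1 (mean 6.76), both below the median of all probes, gave -0.14 and -0.03. No cell cycle gene passed without either wild type smoke array, 2 passed without either Spp1-/- array, 6 without wild type air replicate 2 and 14 without wild type air replicate 1. The calls of single genes on this list thus depended on which arrays entered, while the log2 fold changes of Cdca8, Cdc20, Nusap1 and Mcm5 without a wild type smoke array lay between 0.61 and 1.42.

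Marker genes of other lung cells moved with the same contrast. Of 18 lung epithelium genes, 15 fell and 0 rose, with a median of -1.90 (adjusted p = 1.81e-10; adjusted p = 0.23 with an estimated correlation). Of 13 endothelium genes, 12 fell, with a median of -2.54 (adjusted p = 3.42e-11; adjusted p = 0.18 with an estimated correlation). All 14 fibroblast and smooth muscle genes fell, with a median of -2.40 (adjusted p = 1.03e-11; adjusted p = 0.18 with an estimated correlation). Adjusted over each list alone, 16, 12 and 14 of these genes fell. Over all genes, 8, 10 and 9 fell without wild type smoke replicate 1 and 10, 10 and 9 without replicate 2. Tmem100 and Emcn, both endothelial genes, changed by -3.12 and -2.75. Bgn and Inmt, genes of mesenchymal cells, changed by -2.76 and -1.95, and the surfactant protein gene Sftpa1 by -3.25. Of 11 B cell genes, 7 fell, the same number as when adjusted over the list alone, with a median of -0.86 (adjusted p = 8.11e-05; adjusted p = 0.18 with an estimated correlation). The B cell receptor component Cd79b changed by -2.65 and Fcmr by -2.57, and 3 B cell genes fell without wild type smoke replicate 1 and 4 without replicate 2. Of 10 genes of NK cells and cytotoxic lymphocytes, 1 fell, the perforin gene Prf1 at -1.92, also when adjusted over the list alone, and 3 fell without wild type air replicate 1. Prf1 lost its call without wild type smoke replicate 1 (adjusted p = 0.121), without wild type air replicate 2 (adjusted p = 0.0545) and without either Spp1-/- array (adjusted p = 0.0648). Their median was -0.43 (adjusted p = 0.0409; adjusted p = 0.23 with an estimated correlation). The list's call was lost without wild type air replicate 1 (adjusted p = 0.0739) and without wild type smoke replicate 2 (adjusted p = 0.0606).

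The other lists did not pass as groups in this fit, although single members did. On the list of MHC class II presentation and co-stimulation (median -0.04, adjusted p = 0.295), 4 of 20 genes rose and 8 fell, 5 and 9 adjusted over the list alone. The falls included the invariant chain gene Cd74, from 13.91 ± 0.04 to 12.94 ± 0.01, and H2-Ab1, from 13.74 ± 0.06 to 12.89 ± 0.08. Neither passed without wild type smoke replicate 1 (adjusted p = 0.0628 and 0.0642) or replicate 2 (adjusted p = 0.0579 and 0.0755). On this list 1 gene rose and 1 fell without replicate 1, 0 and 2 without replicate 2, and 2 and 4 without either Spp1-/- array. The interferon response list had a median of -0.06 (adjusted p = 0.218), with 1 of 36 genes higher and 4 lower, also when adjusted over the list alone, 1 and 1 without either wild type smoke array, and 5 and 5 without wild type air replicate 1. Ifit3 fell from 11.68 ± 0.38 to 9.29 ± 0.06, while Irf7, an interferon-induced transcription factor gene, stood at 7.50 ± 0.23 and 7.21 ± 0.11 and did not pass (adjusted p = 0.39). Antioxidant and xenobiotic genes had a median of 0.25 (adjusted p = 0.203), with Slc7a11, a cystine transporter gene, at 3.02 and the glutathione transferase gene Gsta3 at -2.87. The medians were -0.04 for the cytokines of Th17 polarisation and the interleukin-12 family (adjusted p = 0.725), 0.16 for alternative activation (adjusted p = 0.295) and 0.17 for osteopontin receptors (adjusted p = 0.925). They were -0.19 for immediate-early and isolation stress genes (adjusted p = 0.0563), 0.42 for alveolar macrophage (adjusted p = 0.295) and 0 for dendritic cell markers (adjusted p = 0.718). For monocyte, neutrophil and T cell markers the medians were -0.17 (adjusted p = 0.053), -0.36 (adjusted p = 0.137) and -0.17 (adjusted p = 0.0843). With single arrays left out, the stress gene list passed downward without wild type air replicate 1 (adjusted p = 0.0288) or wild type smoke replicate 2 (adjusted p = 0.0471). The monocyte and T cell lists did so without wild type smoke replicate 1 (adjusted p = 0.0472 and 0.0311). Only 4 genes each were measured for basophils, mast cells and eosinophils and for erythroid cells, too few for the list test, with medians of -1.44 and -1.02. Of the 21 lists tested, 9 passed with the preset correlation and 0 with estimated correlations.

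**Figure D1:**
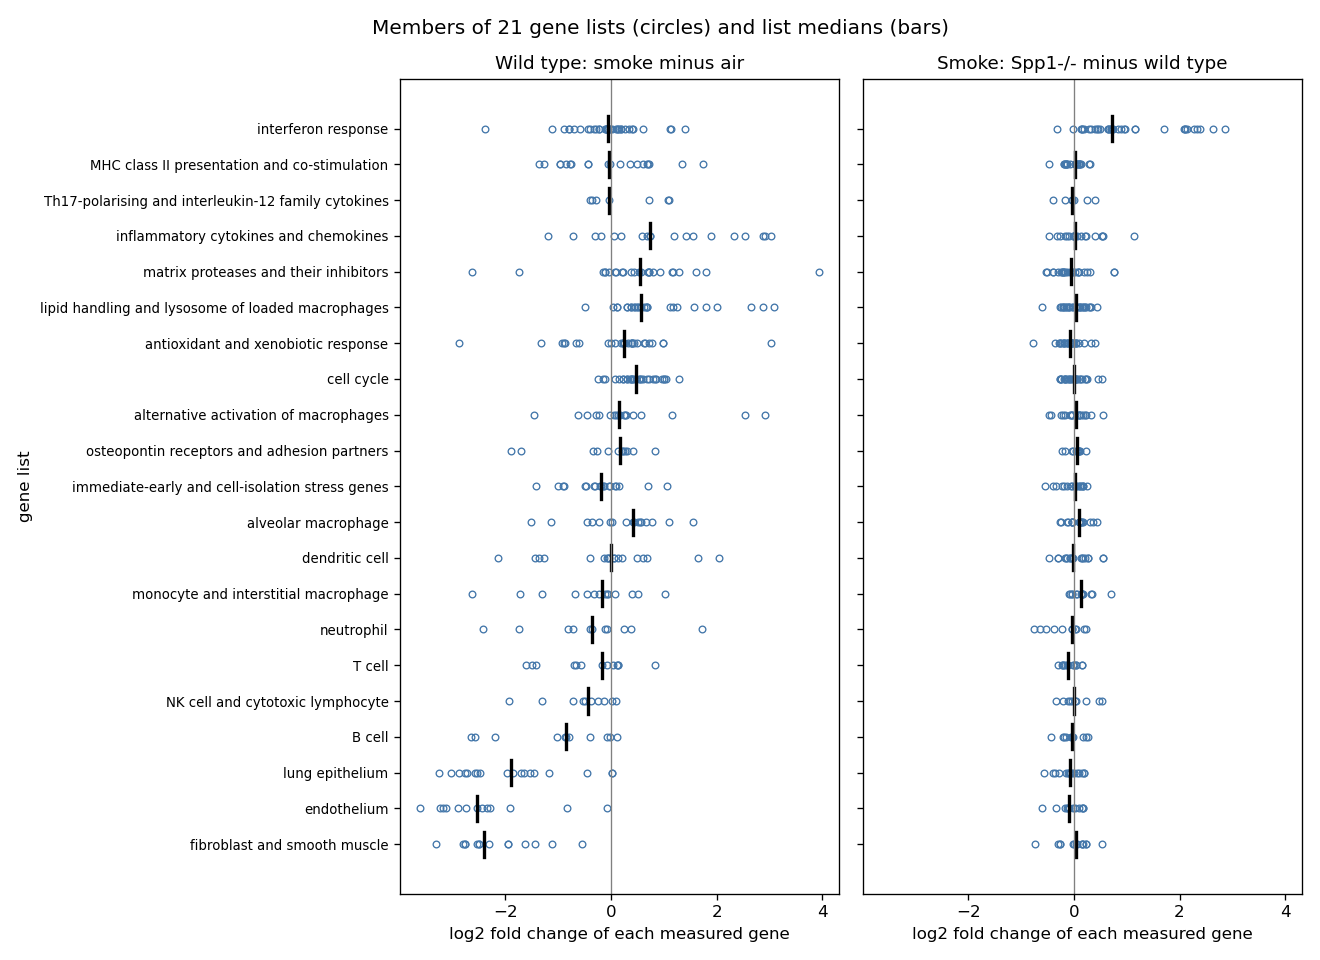
Each circle is the log2 fold change of 1 measured gene and each black bar the median of its list, for smoke minus air in wild type (left) and Spp1-/- minus wild type under smoke (right). The medians of lung epithelium (-1.90), endothelium (-2.54) and fibroblast genes (-2.40) lie to the left in the first comparison, and the median of the interferon response list (0.73) lies to the right in the second.

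The second comparison asked how cells without Spp1 differed from wild type cells when both had been exposed to smoke. The smallest p-values belonged to Usp18, Ifi27l2a, Ifit3 and Oasl2, interferon-stimulated genes with higher values in Spp1-/- cells. In the fit of all arrays, no single gene passed adjustment over all genes. Usp18, which encodes a regulator of interferon signalling, stood at 9.27 ± 0.17 (SD, n = 2) in wild type smoke and 11.55 ± 0.05 in Spp1-/- smoke, a 4.87-fold difference with limma adjusted p = 0.0751. Ifit3 stood at 9.29 ± 0.06 and 12.17 ± 0.09 (adjusted p = 0.0751), Ifi27l2a at 10.57 ± 0.19 and 12.67 ± 0.05 (adjusted p = 0.0751), and Oasl2 at 10.62 ± 0.25 and 13.01 ± 0.11 (adjusted p = 0.0822). Irf7 stood at 7.21 ± 0.11 in wild type smoke, below the median of all probes, and at 8.92 ± 0.31 in Spp1-/- smoke, a log2 difference of 1.71 ± 0.20 (SE) that did not pass (adjusted p = 0.212). A dimmer probe of Usp18 (mean 6.96, below the median of all probes) and of Ifit3 (mean 7.48) gave -0.01 and -0.06. With only the 2 groups in the fit, Ifit3 (limma adjusted p = 0.0152) and Usp18 (adjusted p = 0.0411) passed. Ifi27l2a and Oasl2 passed there too (adjusted p = 0.0448 each).

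Of the 12382 genes, 0 passed the adjusted threshold in limma and 540 had an unadjusted p under 0.05, fewer than the 619 that chance alone gives. Of these 540, 335 were higher and 205 lower in Spp1-/- cells. Under some other settings between 6 and 9 genes passed, all higher in Spp1-/- cells. These settings were an intensity trend with a robust prior, array weights, only the 2 groups in the fit, and a stricter brightness filter. Leaving out either wild type air array gives the same genotype fit as the 2 groups alone, because a lone air array adds no spread. This comparison was simulated in 20 draws with 36 changed genes each. Of these, 0% were recovered at a log2 change of 1, 76% at 2 and 90.8% at 3. The draws raised all 36 genes alike, with the same spread in every group, unlike the data. In the data Ifit3 (2.87), Oasl2 (2.39), Usp18 (2.28) and Ifi27l2a (2.1) did not pass with all 6 arrays. Changes of these sizes could thus be missed as well as smaller ones.

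As a group, the interferon response list lay higher in Spp1-/- cells. Of its 36 measured genes, 34 had positive differences, 18 passed when adjusted over the list alone, all upward, and 0 over all genes. The median log2 difference was 0.73 (camera adjusted p = 2.37e-41). The call was lost with an estimated correlation of 0.19 (camera adjusted p = 0.22), where the test rests on 3 residual degrees of freedom and no list passed. That run changed the correlation and the degrees of freedom together, and their parts in the lost call were not separated. The list was fixed before the data were examined, although what is known of the study already named Irf7, 1 of its members. It was 1 of 21 lists tested and the only list to pass in this fit. In wild type air, Usp18, Ifi27l2a and Oasl2 had values of 9.36 ± 0.16, 10.68 ± 0.13 and 11.06 ± 0.21, near those of wild type smoke, whereas Ifit3 had 11.68 ± 0.38.

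Outside this list, Rassf6 had the smallest p among genes that were higher in Spp1-/- cells (difference 1.55, adjusted p = 0.108), from a wild type value of 7.15 below the median of all probes. In the other direction, Ccng2, the cyclin G2 gene, stood at 10.14 ± 0.26 in wild type and 8.78 ± 0.01 in Spp1-/- cells (adjusted p = 0.186), and Stbd1 at 9.30 ± 0.01 and 8.01 ± 0.26 (adjusted p = 0.293), both among the 100 measured genes nearest to Spp1. The immediate-early gene Egr1 differed by -0.55, the asparagine synthetase gene Asns by -0.61 and Fcrls by -0.54 (limma adjusted p = 0.69 each). A dimmer probe of Asns (mean 6.86) and of Fcrls (mean 6.95), both below the median of all probes, gave 0.03 and 0.04. None of these genes passed.

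The lists that had moved with smoke in wild type had medians near 0 between the genotypes. The median was 0.04 for lipid handling and lysosome (adjusted p = 0.809), -0.06 for proteases (adjusted p = 0.519), 0.02 for cytokines and chemokines (adjusted p = 0.565) and 0 for cell cycle (adjusted p = 0.902). Mmp12 stood at 13.35 ± 0.23 in wild type and 13.44 ± 0.25 in Spp1-/- smoke, and Trem2 at 12.84 ± 0.04 and 12.60 ± 0.01. Markers of lung epithelium (-0.07), endothelium (-0.10), fibroblasts (0.05), T cells (-0.11), B cells (-0.03) and NK cells (0) also had medians near 0, with adjusted p between 0.519 and 0.809. The MHC class II list had a median of 0.03 (adjusted p = 0.902), the Th17-polarising cytokines -0.04 (adjusted p = 0.809) and the osteopontin receptors 0.07 (adjusted p = 0.809). The list next closest to the threshold was that of monocytes and interstitial macrophages, with a median of 0.14 (adjusted p = 0.0803). With single arrays left out, the epithelium list passed downward without wild type smoke replicate 1 (adjusted p = 0.00166) and the T cell list without wild type smoke replicate 2 (adjusted p = 0.036). Without Spp1-/- smoke replicate 1, the antioxidant, neutrophil and epithelium lists passed downward and the alveolar macrophage and monocyte lists upward (adjusted p between 0.0162 and 0.0404). The remaining medians were -0.07 for antioxidant genes, 0.04 for alternative activation, 0.03 for stress genes, 0.09 for alveolar macrophage, -0.02 for dendritic cell and -0.04 for neutrophil markers. A p that misses the threshold does not show that these lists were alike.

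**Figure D2:**
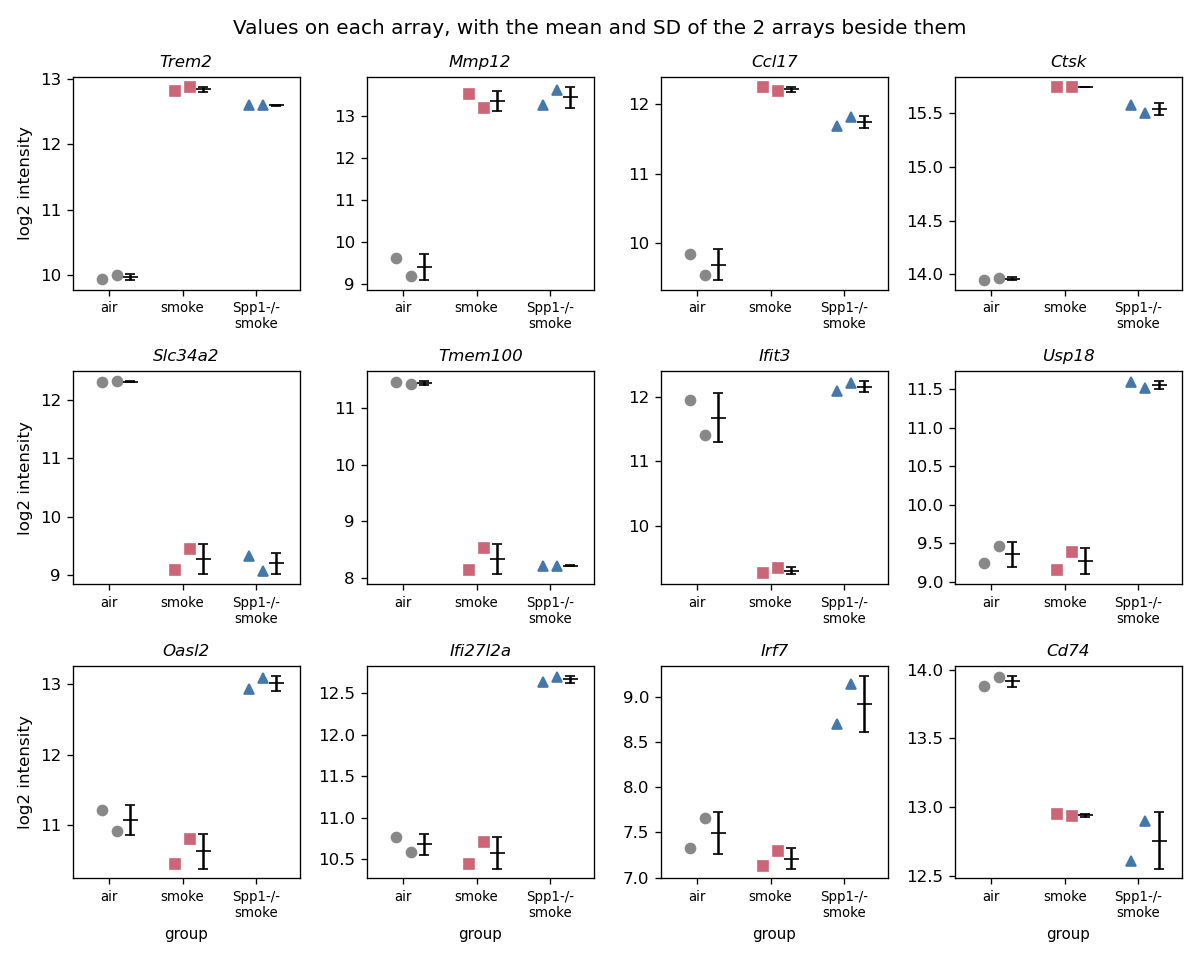
Deposited log2 intensity of 12 genes on each of the 6 arrays, with 1 symbol per array and, beside each pair, the mean and SD of the 2 arrays; the vertical axes differ between panels and do not start at 0. Trem2, Mmp12, Ccl17 and Ctsk lie higher and Slc34a2 and Tmem100 lower in both smoke groups than in air, while Ifit3, Usp18, Oasl2, Ifi27l2a and Irf7 lie higher in Spp1-/- smoke than in wild type smoke.

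The third comparison set Spp1-/- smoke against wild type air, which mixes genotype with exposure. Its log2 fold changes are the sums of those of the first 2 comparisons, so likeness to either is largely built in. Here 2804 genes passed, 1505 higher and 1299 lower in Spp1-/- smoke, and of the 1327 at 2-fold or more, 551 were higher and 776 lower. Of the 21 lists, 11 passed with the preset correlation and 0 with estimated correlations. As in the first comparison, structural cell markers were lower, with medians of -2.19 for lung epithelium, -2.64 for endothelium and -2.23 for fibroblasts (adjusted p of 0.26, 0.19 and 0.19 with an estimated correlation). Mmp12 was 16.4-fold and Trem2 6.22-fold higher (adjusted p = 0.00184 and 0.00169). Of the 36 interferon genes, 15 were higher and 1 was lower (20 and 1 adjusted over the list alone), with a median of 0.84 (adjusted p = 2.70e-06; adjusted p = 0.28 with an estimated correlation). Usp18 was 4.58-fold and Irf7 2.68-fold higher (adjusted p = 0.00198 and 0.00936), and Ifit3 did not pass (adjusted p = 0.148). The count of all genes was 855 without Spp1-/- smoke replicate 1 (364 higher, 491 lower), 673 without Spp1-/- smoke replicate 2 (288 higher, 385 lower) and 1842 without either wild type smoke array (910 higher, 932 lower). The interferon genes that rose numbered 8 without Spp1-/- smoke replicate 1 and 7 without replicate 2, and Irf7 did not pass without replicate 2 (adjusted p = 0.0582).

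Whether genes moved by smoke in wild type lay the other way in Spp1-/- cells under smoke was examined across genes, which are not independent replicates. No gene was called in both comparisons. At an unadjusted p under 0.05 in each, 302 genes were shared, 199 with opposed and 103 with the same direction, against 91 and 96.9 for independent lists. Both comparisons use the wild type smoke arrays, which alone gives opposed values. The log2 fold changes had r = -0.109 and a covariance of -0.0168. Unchanged groups simulated with 1 common spread gave r = -0.499 and a covariance of -0.034, so that the observed covariance lay above it by 0.0172. A second simulation, chosen after this value had been seen, gave each group its own spread and yielded r = -0.379 and a covariance of -0.018, which leaves a difference of 0.00124. The difference thus depended on how the spread was simulated, and with 2 shared arrays that cannot be split, the excess of opposed genes may come from the sharing. Without Spp1-/- smoke replicate 1 the correlation was 0.016.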

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

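The bounds of the tests in this part were written at different times. Those on the air arrays, the marker lists, single arrays, lymphocytes and called neighbours of Spp1 were written when the correlations between arrays and the values of Irf7 had been seen. Those on dilution and on ATF4 genes followed a first look at the results, with the median of the lipid and lysosome list and the values of Asns known. Those on plasmacytoid cell genes, on each Spp1-/- array over all interferon genes and on neighbours of Spp1 at an unadjusted p were chosen only after related results had been seen.

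Probes without a gene name in the annotation used here lay outside the comparisons and still differed. Of 4303 such probes in the brighter part of the range, 370 passed between smoke and air in wild type, 162 of them higher and 208 lower after smoke. By the same test 1 passed between the genotypes under smoke and 394 between Spp1-/- smoke and wild type air.

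Many more genes differed between smoke and air (2645) than between the genotypes under smoke (0). With only the groups compared in each fit, the counts were 1489 and 6. Without wild type air replicate 1 and replicate 2, 3858 and 2768 genes passed, which cannot tell whether a single air array was aberrant. A lone air array adds no spread of its own to the fit, so an aberrant array left alone could also give many calls. Across all probes, air replicate 2 correlated less with every smoke array (Pearson r from 0.9368 to 0.9451) than air replicate 1 did (0.9535 to 0.9589). Another mix of cells in the air preparations is consistent with the marker lists, of which 4 of 6 (B cell, epithelium, endothelium, fibroblast) had medians beyond 0.5 in size. Abundant transcripts moved with them, Sftpc from 14.90 in air to 12.18 in smoke and Inmt from 15.75 to 13.79, and none of these lists' measured genes stood on another list; the labels name no sort that would remove such cells. Whether dilution of macrophage RNA by structural cell RNA could give the whole rise of the lipid and lysosome list cannot be told apart from a change within macrophages, because its median exceeded that of general leukocyte genes by 0.27 (two-sided permutation p = 0.059 over 100000 resamples), short of the bound of 0.3 that had been written after that first look, and an effect of smoke itself stays open.

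The interferon response list had a median difference of 0.73 between Spp1-/- and wild type cells under smoke, a pattern that Irf7 values seen early had prompted. It passed as a group only with the preset correlation (camera adjusted p = 0.22 with an estimated correlation, on 3 residual degrees of freedom). In the fit of all 6 arrays 0 of its 36 genes passed over all genes, and 4 did with only the 2 groups. A single unusual Spp1-/- array is argued against by all 36 genes, whose median above the wild type smoke mean was 0.67 on Spp1-/- smoke replicate 1 (lower quartile 0.27) and 0.8 on replicate 2 (0.49). Only 3 of the 36 had 1 array within 0.2 of that mean and the other above it. That 100% of the 18 genes that passed over the list alone had both Spp1-/- arrays above both wild type arrays by at least 0.2 decides nothing, because these genes were picked for the difference. More lymphocytes are argued against by the T, B and NK cell medians. The farthest of them from 0 was -0.11, against 0.73 for the interferon list. A list of 8 plasmacytoid dendritic cell genes had a median of 0.09, with 5 above and 3 below 0. Its members ran from -0.64 for Cox6a2 to 0.57 ± 0.3 (SE) for Pacsin1, with Siglech at -0.12 ± 0.3. With that spread, the list argues only weakly against more plasmacytoid dendritic cells. An effect of the genotype and an unrecorded difference in housing, infection or handling between the groups both stay open, since the design does not separate them, and the pattern may be either.

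Genes near a targeted locus can differ because flanking DNA of the stem cell strain is carried along. With 0 genes called among the 100 nearest measured neighbours of Spp1, the planned test decided nothing. With only the 2 groups in the fit, 1 neighbour, Slc10a6, was among the 6 genes that passed (adjusted p = 0.0448). At an unadjusted p under 0.05, 9 of 100 neighbours (9%) and 44 of 675 other genes of the chromosome (6.52%) differed, with a two-sided Fisher exact p = 0.393, against 487 of 11607 genes elsewhere (4.2%). Flanking DNA as a source of such differences, among them Ccng2 (-1.36, adjusted p = 0.186), Stbd1 (-1.3, adjusted p = 0.293) and Slc10a6 (1.53, adjusted p = 0.361), could thus not be excluded.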

How the results depend on the processing

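Alternatives with a stricter brightness filter, without the floor and with centring on the kept genes were chosen after the data had been seen. Planned settings that need the unused table were not run: neqc with an offset of 50, normexp with quantile normalization, no background correction and a stricter detection filter; Spp1 had no value under any setting.

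Genes called for smoke in wild type numbered 1489 with only the 2 groups compared, 1295 at 2-fold or more, and 743 to 3858 with arrays left out in turn; the remaining settings gave 2105 to 2655. Spp1-/- smoke against wild type air gave 1842 with only the 2 groups, 1327 at 2-fold or more, and 673 to 4035 with arrays left out. Between the genotypes under smoke, 7 genes passed with an intensity trend and robust prior, 9 with array weights, 6 with only the 2 groups and 8 under the stricter brightness filter, and 0 to 6 with arrays left out; 5, 6, 4 and 7 of those in the first 4 settings were interferon list members. No filter, probe means, the replicate block, removal of the floor and centring gave 0. Counts moved both ways when arrays or groups were left out. Leaving out 1 array of the group not compared gives the same fit as only the 2 groups, so these are not separate settings. The fit of all 6 arrays shares 1 spread per gene among the groups, so the spread of the air arrays enters the genotype comparison. The median SD of a gene was 0.149 in wild type air, against 0.091 in wild type smoke and 0.087 in Spp1-/- smoke. The fit of only the 2 groups leaves out the spread of the air arrays, and there 6 genes passed between the genotypes, against 0 with all arrays. That fit also changes the prior and the residual degrees of freedom, so it does not isolate the spread. How far the spread accounts for the other counts was not tested.

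With estimated correlations, 0 lists passed in either comparison, against 9 and 1. For smoke in wild type, 9 to 11 passed under the other settings, where the monocyte, T cell or stress gene list was added in 9 settings, downward each time. Without a filter 2 lists passed between the genotypes, and 1 to 6 with arrays left out, most without Spp1-/- smoke replicate 1. The interferon list passed in that comparison under every setting but the estimated correlation, with medians from 0.67 to 0.96. The correlation of the 2 comparisons ranged from -0.242 (without wild type smoke replicate 2) to 0.016 (without Spp1-/- smoke replicate 1), and was -0.208 without Spp1-/- smoke replicate 2. Cd8b1, called higher in smoke at 0.83, was -0.17 as the mean of its kept probes. Its other probes gave -0.64 and -1.17, the first of them below the brightness filter and so not in that mean.

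The replicate block gave 2248 genes for smoke, 0 between the genotypes and 2367 for Spp1-/- smoke against air. Deviations of same-numbered arrays correlated at 0.137, -0.082 and -0.029. With so few arrays per group, these values cannot show whether arrays of the same number share more than that number. Differences of genes near the floor of 6.619 are compressed by an unknown amount.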

Other observations

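All gene lists in this part were written after the data had been looked at, with Asns, H2-K1, H2-T10 and H2-M2 already seen, and are adjusted over 5 lists.

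Genes of the ATF4 and amino acid stress response tended upward after smoke in wild type. Of 21 measured genes, 9 rose and 2 fell, with a median log2 fold change of 0.81 (camera adjusted p = 0.00441; adjusted p = 0.11 with an estimated correlation). Without Asns, which had prompted the list, the median over 20 genes was 0.68 (adjusted p = 0.00792). Trib3, a pseudokinase gene induced by ATF4, rose from 9.20 to 11.84 and the folate enzyme gene Mthfd2 from 11.72 to 13.16, while Nupr1 and Atf5 fell by 1.05 and 0.80 and Atf4 itself differed by 0.06 (adjusted p = 0.796). That Asns rose as part of a shared response is consistent with the list median of 0.81, as a hypothesis tested on the data that prompted it. Other cell mixes in the air samples bear on this list as well. Of 14 glycolysis genes, 5 rose (median 0.35, adjusted p = 0.00792; adjusted p = 0.11 with an estimated correlation). Of 31 general leukocyte and myeloid genes, 9 rose and 1 fell (median 0.29, adjusted p = 0.00792; adjusted p = 0.11 with an estimated correlation). The sterol synthesis list had a median of 0.25 (adjusted p = 0.324).

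MHC class I presentation genes had higher values in Spp1-/- than in wild type cells under smoke as a list. The median difference over 17 genes was 0.35 (camera adjusted p = 1.93e-08; adjusted p = 0.077 with an estimated correlation). None of them passed over all genes and 6 passed when adjusted over the list alone. Without H2-K1, H2-T10 and H2-M2 the median over 14 genes was 0.27 (adjusted p = 0.000302). B2m, the shared light chain gene, stood at 13.85 in wild type and differed by 0.54 (adjusted p = 1). The H2 genes are close relatives, so their probes may not separate them; the interferon list, which shares no gene with this one, had a median of 0.73, and between 0.67 (without Spp1-/- smoke replicate 2) and 0.96 (stricter brightness filter) under other settings. Between the genotypes the ATF4 list had a median of -0.13 (adjusted p = 0.00463; adjusted p = 0.2 with an estimated correlation), and the glycolysis, sterol and leukocyte lists had medians of -0.05, -0.02 and -0.02 and did not pass.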
